A study of Mus musculus with 2 samples.

How the data were processed

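H3K36me3 ChIP-seq was done on day 13.5 embryonic mouse forebrain of strain B6NCrl, with a size range of 300 to 500 in the labels. Replicates 1 and 2 are biological replicates per the labels, with 2 and 3 technical replicates that the authors combined. Whether the embryos came from separate litters is not stated, so the spread between replicates may be partly technical. No input control was analysed here.

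The authors deposited 4 peak lists in narrowPeak format on the mm10 build, per the file headers of the accompanying descriptions: a list for each replicate, a pooled list made from the alignments of both, and a replicated list made from the replicate lists and the pooled list. Every one of the 116426 replicated peaks was found as an identical entry of the pooled list, so a replicated peak carries pooled boundaries and pooled values. The aligner, the peak caller and their versions are not given in the sources used here. For each peak the authors deposited a display score, a signal value read here as a ratio (fold over control, from its values and the fold tracks named in the descriptions), a −log10 p-value and a −log10 q-value. The lowest −log10 p-value in the deposited lists was 2.02 in both replicates and 2.03 in the pooled and replicated lists, so the lists reach down to weak peaks. Fold and −log10 values are the authors' own and served only to rank or filter peaks within a list. The score was not used for any result. Peaks were called separately in each replicate, so a library with more reads or stronger enrichment gives more and longer peaks, and a percent of a gene covered by peaks moves with how much was called. No read counts were analysed, so the depth is unknown and no interval from counting could be given.

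Gene models came from the GENCODE release M21 annotation of GRCm38, the assembly that mm10 names, and sequence from the GRCm38.p6 reference. The highest peak end on each chromosome lay within the reference length in all 4 lists. Of 21951 annotated protein-coding genes, the 21728 on chromosomes 1 to 19 and X with a single entry per symbol were used. A gene span runs from its first to its last annotated base, introns included. Percent covered is the share of the span inside peaks, and a gene is marked at 20% or more. Values for a replicate come from its own list; values called replicated come from the replicated list. Because replicated peaks have pooled boundaries, the replicated percentage can exceed both replicate percentages. Errors are the SD over the 2 replicates unless given as the SE across genes. Peaks on chromosome Y and on scaffolds were left out of the tests.

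Replicate agreement and location were tested by shifting all peaks of a list by a random distance around each chromosome, between its first and last called base, 1000 times. A peak counted as shared when at least 50% of its length lay in peaks of the other replicate. The p-values were adjusted over the values of each family by the Benjamini-Hochberg method, here 3 for agreement and 5 for location. Position along the gene used marked genes of at least 10 kb that overlap no other protein-coding gene, and flipped the sign of each gene's difference 100000 times. Each of 23 gene lists was compared with 10000 random lists having as many genes in each of 20 length classes, two-sided, with Benjamini-Hochberg adjustment over the 23 lists. The X chromosome was compared with autosomal genes in the same way. Members of several lists are neighbours in the genome (Hox, Zfp, receptor, histone and protocadherin genes), so membership was also rotated along the genome order of genes, without length matching. The lists cover ribosomal proteins, proteasome, splicing, cell cycle, histone lysine methylation, forebrain progenitors, cortical excitatory neurons, ventral and inhibitory neurons, pan-neuronal genes, adult synaptic genes, protocadherins, imprinted genes, zinc finger genes, receptors, histones and Hox genes. Lists for hepatocytes, striated muscle, erythroid cells, endothelium, microglia, meninges and oligodendrocytes stand for cells a dissection could carry along or that are absent at this age. Several of their members are also used by other cells, such as Tfrc and Slc2a1.

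Named genes followed a rule fixed before the data were examined: the 10 genes of at least 10 kb covered most fully, the 5 with the most covered bases, the 5 under the peaks of highest fold, the 2 most and 2 least covered members of each list, the 3 genes with the widest difference toward each replicate, and 14 genes named in advance (Setd2, Nsd1, Sox2, Pax6, Foxg1, Dlx1, Dlx2, Neurod6, Tubb3, Dcx, Gad1, Hoxa9, Alb and Hbb-bt). Ties were broken by the lower replicate value and then by symbol, and some members are left out for space. Genes outside the rule are said to be named after their values were seen.

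Alternatives chosen before the data were examined were peaks with a q-value of at most 0.01, other overlap rules, equal numbers of top peaks (85234 per replicate), peaks within 1 kb joined, the pooled list, each replicate alone, limits of 10% and 40% for a marked gene, other gene lengths, gene ends left out, rotated lists and genes under 2 kb left out. The alternative with 5′ gene ends alone was chosen after the data were seen.

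The tests were tested on simulated data. Among 200 random lists of 40 genes with no effect, drawn from the 21728 genes, 5.5% were called at 0.05. With the marked share raised by 20 points 71.5% were called, and with 40 points 100%. Marks were simulated independently for each gene by its length class, so these rates need not hold for lists of neighbouring genes. Keeping 50% of 170392 peaks and placing the others at random gave 50.9% shared peaks, and sign flips on 3400 simulated genes called 5% of sets without a difference. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 were used.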

Results

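Trimethylation of histone H3 at lysine 36 (H3K36me3), a mark laid down over transcribed gene bodies, was mapped by ChIP-seq in forebrain of B6NCrl mouse embryos at day 13.5. Tissue of male and female embryos was pooled. The series held 1 group of 2 biological replicates, sequenced as 2 technical replicates for replicate 1 and 3 for replicate 2, so the design implies a comparison between replicates and descriptions of where the mark lies, with no comparison between conditions. The values are the authors' peak lists on the mm10 build, with no read counts, so the depth of each library is unknown and no counting interval can be given. Replicate 1 had 170468 peaks over 105.3 Mb and replicate 2 had 207437 over 126.8 Mb, which is 4.11% and 4.95% of the called bases of chromosomes 1 to 19 and X. The authors' replicated list, made from both replicate lists and the pooled list, held 116426 peaks over 131.0 Mb. A protein-coding gene is called marked where peaks covered at least 20% of its span. Tests over genes or peak positions describe this tissue pool; with 2 replicates, no test across samples was made.

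The first comparison asked how far the replicates placed the mark in the same regions. Most of replicate 1 lay inside replicate 2, while replicate 2 held many further peaks. Of the replicate 1 peaks, 73.4% had at least 50% of their length inside replicate 2 peaks, against 5.36% on average when peaks were shifted along the chromosomes. In the other direction 52.4% of replicate 2 peaks were shared, against 4.45% when shifted. Of all bases in peaks of either replicate, 57.6% were in peaks of both, against 2.55% when shifted. For all 3 values the one-sided circular-shift permutation test gave p = 0.000999 (Benjamini-Hochberg adjusted p = 0.000999), the smallest that 1000 shifts can give. At the level of genes the replicates ranked the 21728 protein-coding genes nearly alike, with a Spearman rho of 0.965 and a Pearson r of 0.983 between their covered percentages; these are correlations across genes, and genes are not independent replicates. The value depends on the overlap rule: with a single partner peak covering at least 50% in both directions, 42.9% of replicate 1 peaks and 35.2% of replicate 2 peaks were shared, against 1.60% and 1.31% when shifted.

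Peaks lay almost entirely within genes. Of the bases in replicated peaks, 94.0% were inside protein-coding gene spans (93.8% ± 0.25 in the separate replicate lists, SD, n = 2), against 41.8% when peaks were shifted. Exons of protein-coding genes held 23.0% of peak bases (23.4% ± 0.98, SD, n = 2) against 3.98% when shifted, a 5.78-fold excess. Shifted peaks could fall outside genes, so the exon excess includes the one for gene spans. Only 4.94% of peak bases (5.02% ± 0.18, SD, n = 2) lay outside all annotated genes, where 51.2% fell when shifted. Regions within 1 kb of the start of any annotated transcript of a protein-coding gene held 14.03% of peak bases (14.1% ± 0.52, SD, n = 2) against 4.09%. That direction turned around for the 5′ ends of the genes themselves: within 1 kb of them lay 0.433% of peak bases against 1.70% when shifted, a measure chosen after the data were seen. Each of these 5 percentages differed from the shifted ones with p = 0.002 in a two-sided permutation test (Benjamini-Hochberg adjusted p = 0.002), the smallest that 1000 shifts can give.

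Along the gene body the mark was nearly absent at the promoter and rose toward the 3′ end. In replicate 1, the 3429 marked genes of at least 10 kb that overlapped no other protein-coding gene had 32.2% of their bases covered 5′ of the gene's midpoint and 61.1% covered 3′ of it. The mean difference was 28.9 percentage points ± 0.39 (SE across genes), and 89.9% of the genes were higher on the 3′ side. In replicate 2, 3888 such genes had 35.0% and 63.8%, a difference of 28.8 points ± 0.36 (SE across genes). Over all 10913 genes of that length without overlap, marked or not, the difference was 11.05 points in replicate 1 and 12.04 in replicate 2. Of these genes 50.8% and 54.2% were higher on the 3′ side. The remainder include genes without a peak, which are equal on both sides, so they were not all higher on the 5′ side. Coverage of the marked genes in replicate 1 went from 0.414% in the kilobase upstream of the gene to 5.49% in the first of 10 equal parts of the gene, 66.2% in part 9 and 43.9% in the first kilobase past the annotated end. The corresponding values in replicate 2 were 0.587%, 7.29%, 68.9% and 50.01%. Exons of the marked genes were covered more than introns, 60.4% against 43.4% in replicate 1 and 63.1% against 46.4% in replicate 2. Exons and introns were not matched for position along the gene, so the rise toward the 3′ end may contribute to that difference. Both kinds of difference had p = 1e-05 in each replicate in a two-sided permutation test that flipped signs over genes, the smallest that 100000 flips can give.

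**Figure D1:**
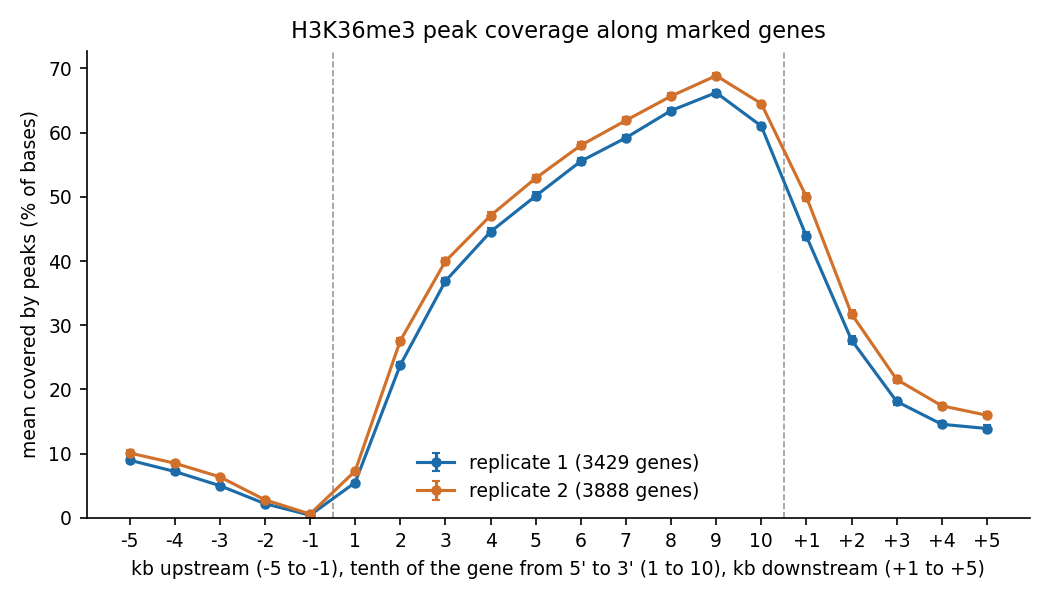
Mean percent of bases covered by H3K36me3 peaks (vertical axis) in the 5 kb upstream of marked genes, in 10 equal parts of the gene from 5′ to 3′ and in the 5 kb downstream (horizontal axis), for replicate 1 (3429 genes) and replicate 2 (3888 genes); bars are the SE across genes. Both curves lie under 1% in the last kilobase before the gene and reach their highest values, 66.2% and 68.9%, in part 9.

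Of the 21728 protein-coding genes, 7302 (33.6%) were marked in the replicated list. Replicate 1 marked 6410 and replicate 2 marked 7234 (mean 6822 ± 583, SD, n = 2), with 6366 genes in both, 44 in replicate 1 alone and 868 in replicate 2 alone. No base of a replicated peak fell in 10860 genes. The 10 most fully covered genes of at least 10 kb were ranked by the replicated list, while the percentages given are means of the replicates. Other genes can therefore have higher means. Among the 10 was Trrap, a scaffold subunit of histone acetyltransferase complexes (chromosome 5, 144767732 to 144859778), covered over 91.4% ± 0.33 of its 92.0 kb (SD, n = 2). Prpf8, the core protein of the spliceosome, had 89.9% ± 0.88, and the splicing factor genes Sf3a1, Sf3b3 and Sf3a3 had 91.0% ± 1.88, 86.5% ± 2.57 and 83.7% ± 7.97 (SD, n = 2). Rnf40, a histone H2B ubiquitin ligase, had 91.9% ± 2.20, Ints1, an Integrator subunit, had 88.7% ± 0.99, and Sin3b, a corepressor, had 88.3% ± 3.00 (SD, n = 2). Phykpl had 89.4% ± 2.87 and the uncharacterised gene 1700109H08Rik had 88.6% ± 0.97 (SD, n = 2). By covered length, Syne2, which links the nucleus to the cytoskeleton, led the genes of ordinary span with 191.1 kb in replicated peaks, followed by Wdfy3 with 139.3 kb and Kalrn with 132.8 kb. Gm20388 and Fgfr2 had 649.3 kb and 257.8 kb, over annotated spans of 4434.9 kb and 2960.9 kb that reach across many other genes. Among the enzymes of the mark itself, Setd2, the H3K36 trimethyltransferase, was covered over 46.7% ± 5.80 and Nsd1, which makes lower H3K36 methylation states, over 58.5% ± 6.88 (SD, n = 2).

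Many of the peaks with the highest fold in the authors' replicated list lay in zinc finger genes. The highest, at 21.5-fold, covered the 3′ end of Zfp146 (chromosome 7, 30160614 to 30164396), followed by peaks in Zfp763 (18.6), Zfp68 (17.7) and Zfp354c (17.2). The fifth, at 16.9-fold, lay in Spred2, an inhibitor of Ras signalling. Of the 100 peaks with the highest fold, 42 overlapped a gene named Zfp, against 2.02% of the whole list (p = 4.03e-44, two-sided Fisher's exact test over peaks, which are not independent of their neighbours; computed after the values were seen). The corresponding counts in the separate lists were 42 in replicate 1 and 43 in replicate 2.

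Gene lists fixed before the data were examined were compared with protein-coding genes of the same length; 23 lists were tested, with Benjamini-Hochberg adjustment over the 23. Lists of cell cycle, splicing, histone lysine methylation, ribosomal protein and proteasome genes were marked far more often than length-matched genes. Cell cycle and mitosis genes were marked in 43 of 45 cases (95.6% against 39.7% of length-matched genes). By replicated coverage they were led by the condensin subunit Ncapd2 and the replicative helicase subunit Mcm2. The replicate means of these 2 genes were 89.6% ± 1.78 and 80.6% ± 3.34 of the span (SD, n = 2). Splicing factors were marked in 68 of 74 cases (91.9% against 38.9%), histone lysine methyltransferases and demethylases in 35 of 39 (89.7% against 37.0%), ribosomal protein genes in 65 of 79 (82.3% against 22.7%) and proteasome subunits in 30 of 39 (76.9% against 37.3%). Kdm4a, an H3K9 and H3K36 demethylase, was covered over 89.9% ± 1.65, Rps15a over 75.7% ± 2.87 and the proteasome ATPase gene Psmc4 over 85.1% ± 1.61 (SD, n = 2). No replicated peak base fell in 8 ribosomal protein genes, among them Rpl36a and Rpl39l, in 5 proteasome genes, among them Psma8 and Psmb10, and in 2 splicing factor genes, Hnrnph2 and Sf3b5. Zfp genes were marked in 248 of 394 cases (62.9% against 39.9%), with Zfp869 at 96.5% ± 1.93 and Zfp2 at 84.7% ± 2.55 (SD, n = 2). Each of these 6 lists had p = 0.0002 in a two-sided permutation test, the smallest that 10000 random lists can give, and an adjusted p of 0.000418. All 6 were also called when membership was rotated along the genome, which keeps neighbours together (adjusted p = 0.000511 in that permutation test).

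**Figure D2:**
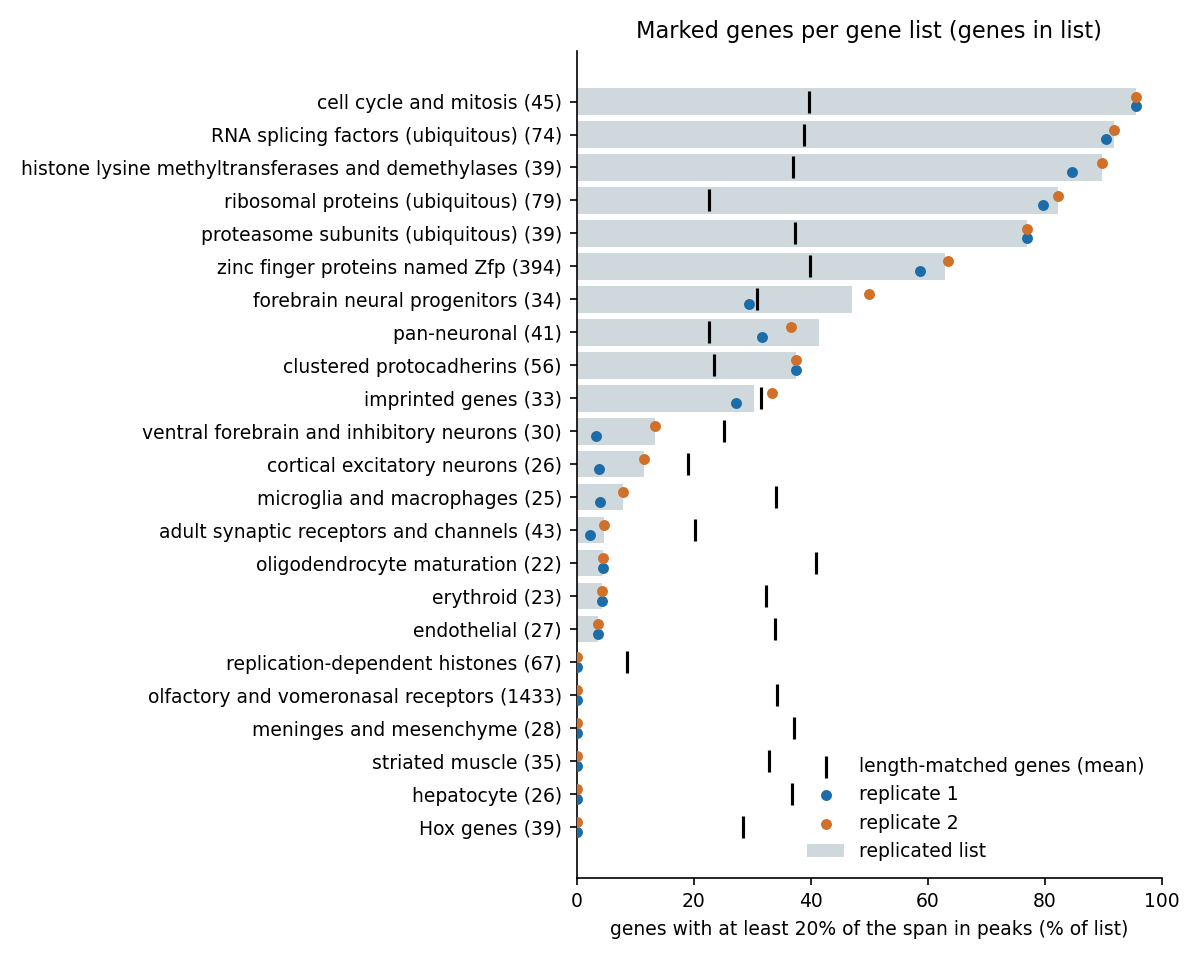
Percent of genes in each of 23 lists with at least 20% of the span in H3K36me3 peaks (horizontal axis), in the replicated list (bars) and in each replicate (points); black ticks are the mean of length-matched random lists, and the number of genes is given in brackets. Cell cycle genes reach 95.6%, and 6 lists (Hox genes, hepatocyte, striated muscle, meninges and mesenchyme, receptors and histones) are at 0.

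Neuronal genes were marked unevenly. Of the 41 pan-neuronal genes 17 were marked (41.5% against 22.6% of length-matched genes, adjusted p = 0.0069, permutation test), with a mean of 34.1% ± 3.45 in the separate replicates (SD, n = 2). The call was lost when membership was rotated along the genome (adjusted p = 0.393) and with 40% of the span required (adjusted p = 0.0506), both from permutation tests. Rotated lists were not matched for length, and 33.6% of all protein-coding genes were marked. The loss on rotation can therefore come from gene length as well as from neighbours. Dpysl2, a regulator of axon growth, was covered over 83.9% ± 2.31 and Crmp1, of the same family, over 50.9% ± 3.36, and the neuronal tubulin gene Tubb3 over 45.0% ± 4.67, while the presynaptic adhesion gene Nrxn1, 1059.4 kb long, had 0.207% ± 0.047 (SD, n = 2). Nefl had 0% in replicate 1 and 16.5% in replicate 2. Dcx, a microtubule protein of migrating neurons that lies on the X chromosome, had 6.05% ± 1.87 (SD, n = 2). Cortical excitatory neuron genes were marked in 3 of 26 cases (11.5% against 19.04%, adjusted p = 0.459, permutation test), namely Cux1 (23.0% ± 3.61), Bcl11a (21.1% ± 3.64, SD, n = 2) and Zbtb18, the last named after its value was seen. Replicate 1 marked 3.85% of this list and replicate 2 marked 11.5%. Neurod6 and Neurod1 were at 0. Ventral forebrain and inhibitory neuron genes were marked in 4 of 30 cases (13.3% against 25.3%, adjusted p = 0.176, permutation test): Gad1, Gad2, Dlx2 and Meis2, the last named after its value was seen. Replicate 1 marked 3.33% of this list and replicate 2 marked 13.3%. Gad1 and Gad2, which make the transmitter GABA, had 17.9% ± 4.93 and 22.8% ± 2.85, while Dlx1 had 3.54% ± 0.92 (SD, n = 2) and Ascl1 had 0%. In the replicated list, which made the calls, Gad1 had 22.3% and Dlx2 had 33.2%. The excitatory list was called below when rotated (adjusted p = 0.0235), and the ventral list when rotated (adjusted p = 0.0361), at 40% of the span (adjusted p = 0.0124) and without replicate 2 (adjusted p = 0.0123), all from permutation tests. Both length-matched shares lie below the 33.6% of all genes, so the 2 calls on rotation may reflect gene length.

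Forebrain progenitor genes differed most between the replicates. Of 34 genes, 16 were marked in the replicated list (47.1% against 30.9% of length-matched genes), which did not pass the test (adjusted p = 0.0678, permutation test). Replicate 1 marked 29.4% of them and replicate 2 marked 50% (mean 39.7% ± 14.6, SD, n = 2), and the list was called above without replicate 1 (adjusted p = 0.0276), with 10% of the span required (adjusted p = 0.00568) and in the pooled list (adjusted p = 0.00622), all from permutation tests. Mean coverage of the 34 genes was 14.3% in replicate 1 and 24.1% in replicate 2, with 29 higher in replicate 2, 1 higher in replicate 1 (Neurog2, named after its value was seen) and 4 equal. Sox2, a transcription factor of neural stem cells, had 0% in replicate 1 and 28.2% in replicate 2. Pax6 had 10.01% and 16.5%, Foxg1, a determinant of the telencephalon, had 18.5% and 27.8%, and Fabp7, a radial glial fatty acid binding protein, had 0% and 12.5%. The intermediate filament gene Vim had 46.0% and 52.5%, and the receptor gene Fgfr3 had 62.8% and 63.8%. Eomes, a marker of intermediate progenitors, was at 0 in both replicates. Among the ventral genes, Dlx2 likewise had 0% in replicate 1 and 20.4% in replicate 2.

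**Figure D3:**
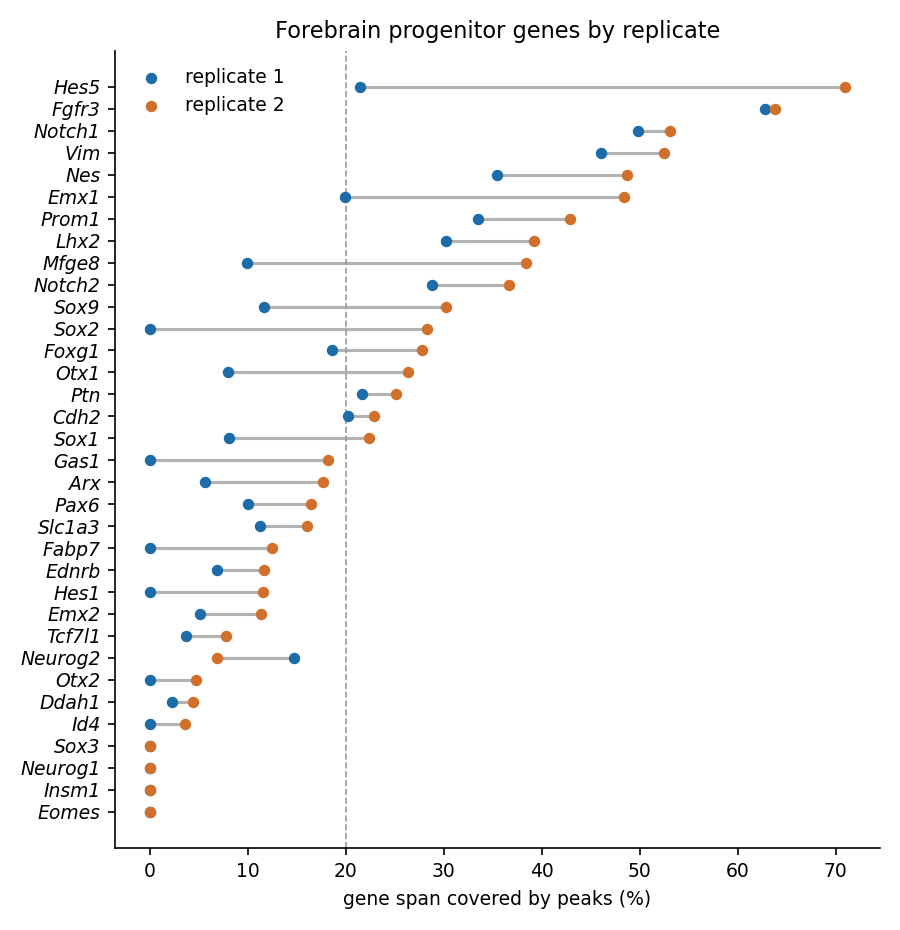
Percent of the gene span covered by H3K36me3 peaks (horizontal axis) for the 34 forebrain progenitor genes (vertical axis) in replicate 1 and replicate 2; grey lines join the replicates and the dashed line is the 20% limit for a marked gene. The replicate 2 point lies to the right for 29 genes, to the left for 1, and both coincide for 4.

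Genes of other tissues and of later stages were rarely marked, as were replication-dependent histone genes, which belong to neither group. No member was marked among 39 Hox genes (28.4% of length-matched genes), 26 hepatocyte genes (36.8%), 35 striated muscle genes (32.8%), 28 meningeal and mesenchymal genes (37.2%) and 1433 olfactory and vomeronasal receptors (34.3%), each with p = 0.0002 in the permutation test, the smallest it can give, and an adjusted p of 0.000418. Hoxa9, a posterior patterning gene, the albumin gene Alb and the adult globin gene Hbb-bt had no peak base in either replicate. None of 67 replication-dependent histone genes was marked, against 8.60% of genes as short (adjusted p = 0.00517, permutation test); the call was lost without genes under 2 kb (adjusted p = 0.0947). Blood and vessel lists had few marked members: 1 of 23 erythroid genes (adjusted p = 0.00427), the transferrin receptor gene Tfrc at 64.0% ± 1.93, and 1 of 27 endothelial genes (adjusted p = 0.000767), the glucose transporter gene Slc2a1 at 41.05% ± 8.0 (SD, n = 2, permutation tests). Oligodendrocyte maturation genes were marked in 1 of 22 cases, Cnp at 76.9% ± 3.39 (SD, n = 2), with an adjusted p of 0.00106 in the permutation test. Cnp overlaps the marked gene Dnajc7.

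Microglia and macrophage genes were marked in 2 of 25 cases (8% against 34.0%, adjusted p = 0.0069, permutation test), a call lost with 10% of the span required (adjusted p = 0.0707). Replicate 1 marked 4% of this list and replicate 2 marked 8%. The marked genes were Fcer1g at 19.3% ± 2.80 (SD, n = 2) and Cd68, named after its value was seen, which was covered over 100% in both replicates. Fcer1g had 23.7% in the replicated list, which made the call, and 17.3% in replicate 1. Both lie directly 3′ of a marked gene on the same strand: Cd68 (chromosome 11, 69664213 to 69666153) is 782 bp from the translation factor gene Eif4a1, and Fcer1g is 487 bp from the mitochondrial complex I gene Ndufs2. Adult synaptic receptor and channel genes were marked in 2 of 43 cases (4.65% against 20.2%, adjusted p = 0.00517, permutation test), the kainate receptor gene Grik5 at 76.4% ± 5.29 and the calcium channel gene Cacna1b at 17.6% ± 4.64 (SD, n = 2). Cacna1b had 22.3% in the replicated list, which made the call. Replicate 1 marked 2.33% of this list and replicate 2 marked 4.65%. The call was lost at 10% (adjusted p = 0.0707), at 40% (adjusted p = 0.0778) and in the pooled list (adjusted p = 0.0622), all from permutation tests. These 11 lists with fewer marked members were also called below when rotated along the genome, without length matching. The adjusted p-values were between 0.000511 and 0.0143 in those permutation tests.

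Imprinted protein-coding genes, of which 33 had an annotated span, were marked in 10 cases (30.3% against 31.6%, adjusted p = 1, permutation test), and single members lay far apart. Nnat, expressed in developing brain and lying within the span of Blcap, was covered over 80.3% ± 4.02 and Igf2r over 58.9% ± 6.08, while Asb4 had 0.322% ± 0.456 (SD, n = 2). Clustered protocadherins, cell adhesion genes whose gamma members share 3′ exons, were marked in 21 of 56 cases (37.5% against 23.5%, adjusted p = 0.0237, permutation test). Pcdhga3 and Pcdhgc5, which overlap at their 3′ ends, had 50.9% ± 0.64 and 48.2% ± 3.25 (SD, n = 2), and Pcdhb1 had 0%. Because spans of this cluster overlap, the same peaks count for several members. The call was lost when rotated along the genome (adjusted p = 0.890), with 10% required (adjusted p = 0.417) and in the pooled list (adjusted p = 0.124), all from permutation tests. Rotated lists were not matched for length, and 33.6% of all protein-coding genes were marked. The loss on rotation therefore does not isolate the effect of neighbours.

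Peaks covered far less of the X chromosome than of any autosome. Replicated peaks covered 0.868% of its called bases against 5.41% of the autosomes, 6.23-fold lower on the X, and the X-to-autosome ratio was 0.141 in replicate 1 and 0.189 in replicate 2. Of 948 protein-coding genes on the X, 98 were marked (10.3%), against 31.2% of autosomal genes of the same length (p = 0.0002, two-sided permutation test, the smallest that 10000 draws can give). The replicate 1 list marked 65 X genes (6.86%) and the replicate 2 list 108 (11.4%). Of the ribosomal protein, proteasome, splicing and cell cycle genes, 204 of 231 on autosomes and 2 of 6 on the X were marked. On the X, replicate 1 marked 16.7% of these and replicate 2 marked 33.3%. The marked X genes were Rps4x, with 25.2% of its span covered in replicate 1 and 28.3% in replicate 2, and Rpl10, with 9.04% and 20.5%, both named after their values were seen; Rpl36a had no peak base, and Hnrnph2 had 0% in replicate 1 and 9.66% in replicate 2. Kdm6a, an X-linked H3K27 demethylase gene, had 4.61% ± 2.74 (SD, n = 2).

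**Figure D4:**
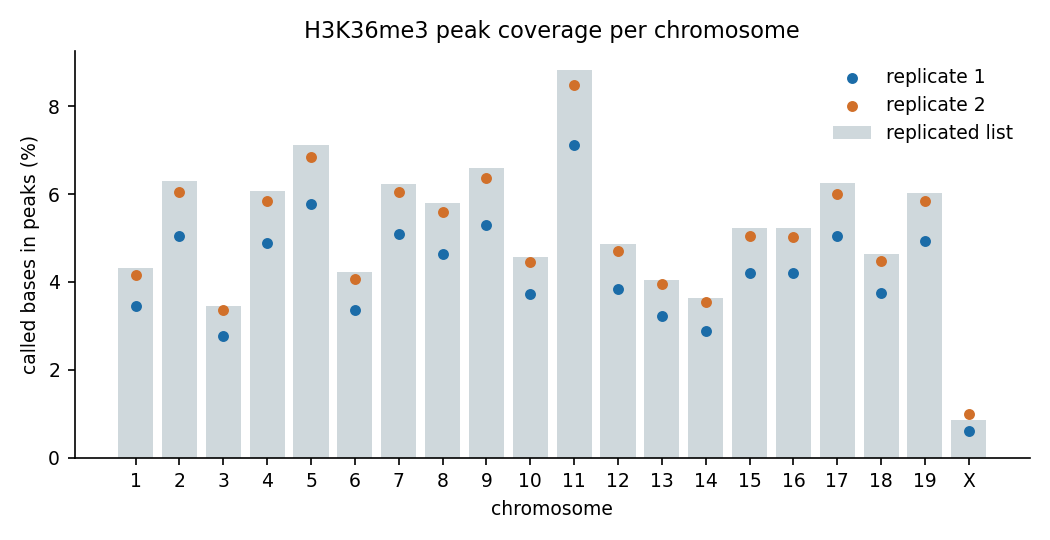
Percent of called bases in H3K36me3 peaks (vertical axis) for chromosomes 1 to 19 and X (horizontal axis) in the replicated list (bars) and in each replicate (points). The X stands at 0.868% in the replicated list, against 5.41% for the autosomes together.

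Replicate 2 covered more of most genes. Of 12222 genes with a peak in at least 1 replicate, 87.8% had the higher coverage in replicate 2, whose list was 1.22 times as long. Among genes of at least 10 kb the differences toward replicate 2 were widest for Dennd6b (20.4% and 51.8%), BC024978 (26.6% and 57.0%) and the mitochondrial exonuclease gene Rexo2 (8.91% and 38.5%). Toward replicate 1 they were widest for Bloc1s6 (40.7% and 28.9%), Kdelc1 (56.8% and 46.3%) and Leprotl1 (47.9% and 39.5%). These are differences between a pair of libraries and have no replicate of their own.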

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

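Chosen after the results were seen were the tests of gene length and of X copy number for the X chromosome and the test of a single library for zinc finger genes. Signal outside the main measurement was present in 3 places. The replicated list held 9 peaks on chromosome Y and 31 on unplaced or unlocalised scaffolds. The pooled list held 75288 peaks that the replicated list leaves out, with a median fold of 2.35, a median width of 237 bp and 90.02% of their bases inside protein-coding genes.

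The X chromosome was covered 6.23-fold less than the autosomes by replicated peaks. This ratio is per called base and the density of genes was not compared, so it is not a difference per gene. The lengths of X genes do not account for their lower share of marked genes. Of X genes 10.3% were marked, below the 28.5% to 34.0% of autosomal genes in the central 95% of length-matched draws. Less unique sequence does not account for the 6.23-fold lower coverage per base. Of 31-mers sampled in X genes, 83.04% occurred once in the reference, which is 92.6% of the autosomal 89.7%. Positions were sampled by base, so short genes weigh little. Repeated sequence was therefore not excluded as a contributor to the lower share of marked genes. A detection limit that takes more from the X, which has fewer copies in male cells, cannot be told apart from a lower level of the mark, because the X-to-autosome ratio in the pooled list was 0.188, within the replicates' 0.141 and 0.189, and the number of reads per library is unknown. Dosage and inactivation of the X in a pool of both sexes may also contribute, and no biological explanation was tested.

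Progenitor genes were covered by 9.84 percentage points more in replicate 2. The difference lay at percentile 100 of 10000 random lists matched on mean coverage and length, whose mean was 5.12 points. It also lay at percentile 100 among lists matched on coverage and GC content. Across genes with a peak, the replicate difference had a Spearman rho of 0.182 with GC percent. The median GC percent was 50.9 for progenitor genes and 45.3 for all genes. Length and GC content were not matched together. Cell cycle genes lay at percentiles 97.15 and 99.6 in those comparisons, pan-neuronal genes at 38.4 and 21.7, and Zfp genes and protocadherins at 0. Erythroid genes lay at 1.07 and 0.54, oligodendrocyte maturation genes at 0.76 and 2.2, and splicing factors at 1.74 and 5.61. Because lists of several kinds lay in the tails, the percentiles cannot tell whether the general excess of peaks or GC content accounts for the progenitor difference. A different share of progenitor cells in the dissected tissue, or enrichment that differs between the libraries, may lie behind this; neither could be tested, no biological explanation was tested, and 23 lists were looked at in 2 ways.

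Of the top 100 peaks by fold, 42 lay in zinc finger genes. Sequence repeated exactly elsewhere in the reference does not account for it. The median zinc finger peak had 96.5% unique 31-mers, the lowest 78.7%, and the other top peaks a median of 96.0%. Nearly identical sequence of paralogs counts as unique here and only called peaks were examined, so such sequence was not excluded. A single library does not account for the excess either. In the replicate where it was smaller, the share among the top 100 was 21.6 times that of the whole list. Their midpoints lay at a median of 82.5% of the gene's length from the 5′ end, against 68.1% for the other top peaks in genes. The control library was not analysed here, so low control signal over these genes stays open, and no biological explanation was tested.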

How the results depend on the processing

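The measure with 5′ gene ends alone was chosen after the data were seen. Among the main results, 1 alternative reversed and 1 moved a value beyond its spread. In the other 72 a tested value kept its direction and its side of the threshold, an untested value stayed within its spread, or a count stayed within 1.5 times the main count, which does not mean that the same genes or lists were called. The excess within 1 kb of transcript starts (14.03% of peak bases) became a deficit of 0.433% against 1.70% when shifted with 5′ gene ends alone; internal transcript starts, which lie inside gene bodies, count in the first measure and not in the second. The Spearman rho between replicates went from 0.965 to 0.968 across genes when genes without a peak were left out. Its spread here came from resampling genes and is not a spread between replicates. The cause was not tested. Shared peaks of replicate 1 ranged from 42.9% to 82.8% over the overlap rules and peak choices, marked genes from 5024 at 40% of the span to 8587 at 10%, and the 3′ excess in replicate 1 from 11.05 points over all genes, marked or not, to 31.5 points with genes of at least 5 kb. Called lists ranged from 6 to 9 above and from 9 to 13 below. Over lists, 167 alternatives kept the call, 10 lost it and 7 gained it, with none turned around; those are given with each list. Leaving out a replicate changed the progenitor call (without replicate 1) and the ventral forebrain call (without replicate 2). For single named genes, 347 alternatives stayed within the replicate spread and 149 did not. Depth is unknown, so weakly covered genes cannot be called free of the mark.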

Other observations

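The test of continuation past gene ends was chosen after the result was seen. Non-coding genes were covered to different extents. Of 4814 lincRNA genes that overlap no protein-coding gene, 72 were marked (1.496%; 1.20% in replicate 1 and 1.58% in replicate 2), against 33.6% of protein-coding genes, without matching for length. Processed transcripts that overlap no protein-coding gene were marked in 18 of 338 cases (5.33%). Where overlaps with protein-coding genes were allowed, 532 of 2958 antisense genes (17.99%) and 118 of 788 processed transcripts (14.97%) were marked. The lincRNA genes with the most covered bases, named after their values were seen, included Mir9-3hg, host of the neural microRNA miR-9 (57.4% ± 5.33 of 34.4 kb, SD, n = 2), Pantr1 (15.2% ± 2.37) and Ftx, a regulator of Xist on the X chromosome (19.5% ± 6.402, SD, n = 2). Among non-coding members of the imprinted list, the maternally expressed transcripts of a shared cluster on chromosome 12 were covered, Meg3 over 41.5% ± 4.25, Mirg over 48.9% ± 4.83 and Rian over 17.2% ± 0.83 (SD, n = 2). Peg13 had 20.9% ± 6.57, Airn 4.75% ± 1.13 and Kcnq1ot1 3.56% ± 0.42 (SD, n = 2), and H19 had no peak base.

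The genes under the longest peaks and nearest to the longest intergenic peaks are named here after their values were seen. The longest unbroken peak ran for 41903 bp in Ubr4 (chromosome 4, 139444253 to 139486155), followed by 35017 bp in Prrc2b, 34183 bp in Kmt2d, 33567 bp in Trrap and 32039 bp in Dync1h1, a dynein heavy chain gene.

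Intronless genes were hypothesised to be marked less often, and genes with a single exon block stood for them. Exons of all transcripts of a gene were merged, so a spliced gene with a transcript that keeps its introns can also have a single block. Of 1175 genes with a single exon block outside the receptor and histone lists, 108 were marked (9.19%; 7.32% in replicate 1 and 9.45% in replicate 2). Of the 583 that had enough multi-exon genes of their length for matching, 13.9% were marked, below the 23.2% to 29.0% in the central 95% of 10000 random lists, which is consistent with the hypothesis. The splicing factor gene Sf3b5, with 1 exon block, had no peak base. Matching was for length alone, so a lower activity of such genes may account for the difference as well and was not tested.

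Peaks outside annotated genes may largely be continuations past the 3′ ends of marked genes. Of their bases in the replicated list, 78.5% lay within 5 kb downstream of a marked gene and 7.31% within 5 kb upstream, with 76.5% and 7.18% in replicate 1 and 73.2% and 7.05% in replicate 2. The intergenic zones were about equally large, 19.2 Mb downstream and 20.3 Mb upstream. The longest such peak ran for 6667 bp, 538 bp downstream of Rsl24d1 (chromosome 9, 73123872 to 73130538). Not all lay downstream: the next longest, of 6377 bp, lay 38607 bp upstream of Scaf8, and a further one of 3910 bp lay 903 bp upstream of Slc17a9. Cd68 and Fcer1g, the marked members of the microglia list, lie 782 bp and 487 bp past the ends of Eif4a1 and Ndufs2, so their coverage may come from the neighbour's mark; microglia genes without such a neighbour were not examined for this.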
